A study of Mus musculus with 8 samples.

How the data were processed

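RNA was taken from 8 samples of the mouse alpha cell line αTC1-6, 4 transfected with an empty plasmid and 4 with a Yy1 plasmid. Per the labels' protocols, RNA was extracted with Trizol and columns, selected for poly(A) and made into strand-specific libraries. The submitters' processing notes name fastp, kallisto and the mouse build GRCm39, without versions, and do not say how transcripts were summed to genes. The deposited table holds estimated counts, not scaled for depth, for 75078 Ensembl genes in 8 columns, and per the labels the sample descriptions tie each column to a sample. No column was left unused. These expected counts, as deposited by the authors, were partly fractional and were rounded to whole numbers before any test.

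Gene symbols and types came from GENCODE mouse release 21, an annotation of an older build than the one the notes name, so no coordinates are given. It matched 48278 of the IDs, and the rest are called models without a symbol. Whether newer annotations name them was not checked here. Estimated counts divide reads that match several transcripts, so values of genes with near-identical copies, such as histones and ribosomal protein genes with pseudogenes, and of genes that overlap others are uncertain.

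Counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 15916 genes. The common biological coefficient of variation was 0.0567. The standard error of a log2 fold change was its size divided by the square root of F. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Yy1 left out and at least 5 tested members, beside camera with an estimated correlation and fry. A list's mean difference in the results is that of its members' log2 CPM. Single values per library were compared by exact permutation over 70 arrangements, on log2(CPM + 1) for genes. CPM values per gene use TMM-scaled library sizes.

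The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule always named Yy1, Gcg and some further genes, and some genes that it or the calls would name are not reported here. It added the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 2 and libraries that do not overlap. Symbols starting with Gm or AC or ending in Rik, and genes without a symbol, were left out of that part. Up to 4 members of each list with the smallest p were added. Names outside the rule are said to be so where they appear.

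Alternatives were RLE and upper-quartile scaling, library size alone, 3 other filters, DESeq2 1.42.0, limma-voom, Yy1 left out before scaling, 1 surrogate variable (sva 3.50.0), glmTreat at a fold change of 1.2, estimated correlation, fry and each library left out. Added after seeing the data were thinning to equal depth, testing only genes with a symbol or only protein-coding genes, and odd or even sample number as a term. The planned test of YY1 motifs in promoters was not run, because no genome sequence of a matching build was used here. Motifs at transcript starts were searched instead in GENCODE transcripts, and B1 and B2 repeats with BLAST 2.17.0 (e-value limit 1e-10).

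The edgeR and camera steps were tested on 5 simulated data sets of this comparison, with on average 15669 genes tested and 200 changed in each. Genes changed by 1.2-fold were recovered in 59.1% of cases, by 1.5-fold in 98.2% and by 2-fold in 99.1%, all at an average log2 CPM of at least 2. Of all calls in the simulations 7.72% fell on unchanged genes, above the nominal 5%. Of 150 unchanged lists 5 had a camera p under 0.05, and 5 of 5 lists shifted by 1.1-fold did. The simulated genes vary independently, unlike the members of real lists.

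Totals ran from 20679804 to 33347445 counts per library. A count of 0 allows up to 3 counts, or 0.145 CPM in the smallest library and 0.09 CPM in the largest. Limits and intervals on counts cover counting error only, since reads are not independent molecules. Limits on a share or a median of genes take genes as the units instead. Replicate pairs of a group differed by more than sampling noise, with a chi-square per degree of freedom between 2.92 and 13.4, so no library was counted as a copy of another.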

Results

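Messenger RNA was measured in αTC1-6 cells, a mouse pancreatic alpha cell line that makes and secretes glucagon. The cells had been transfected with either an empty plasmid or a plasmid that overexpresses Yy1, a zinc finger transcription factor that binds promoters and enhancers and can activate or repress genes. Each group held 4 libraries, numbered 31, 32, 33 and 34 for the empty plasmid and 45, 46, 47 and 48 for the Yy1 plasmid. Cells were transfected 24 h after seeding in DMEM labelled 11 mM, and the labels used here do not give the time of harvest. The labels give separate samples but do not say that these came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Nor do the labels say whether the groups were handled together. Besides Yy1 itself, a difference in handling thus cannot be told apart from an effect of the plasmid. Summed estimated counts per library were 30570601, 26512862, 20679804 and 27907363 with the empty plasmid and 32572081, 29680177, 33347445 and 32123367 with the Yy1 plasmid, in the order of the sample numbers. The smallest library was thus empty plasmid 33 and the largest Yy1 plasmid 47. The difference in depth between the groups gave a two-sided exact permutation p of 0.0571.

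The single comparison in the design asks what overexpression of Yy1 does to the transcriptome of alpha cells. Yy1 itself (ENSMUSG00000021264) stood at 175 ± 5.37 CPM (SD, n = 4) with the empty plasmid and at 5233 ± 464 CPM (SD, n = 4) with the Yy1 plasmid. This was a 29.9-fold rise, with a log2 fold change of 4.90 (SE 0.0619; edgeR quasi-likelihood test, adjusted p = 7.38e-24). The libraries with the empty plasmid held 5441, 4464, 3565 and 5053 Yy1 counts, against 192259, 142992, 170099 and 162719 in those with the Yy1 plasmid. The exact permutation test of log2(CPM + 1) gave a two-sided p of 0.0286, the smallest that 4 against 4 libraries allow. With the Yy1 plasmid, Yy1 made up 0.522 ± 0.0469% of all counts (SD, n = 4). A count per gene cannot separate transcript of the plasmid from that of the cells' own gene.

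**Figure D1:**
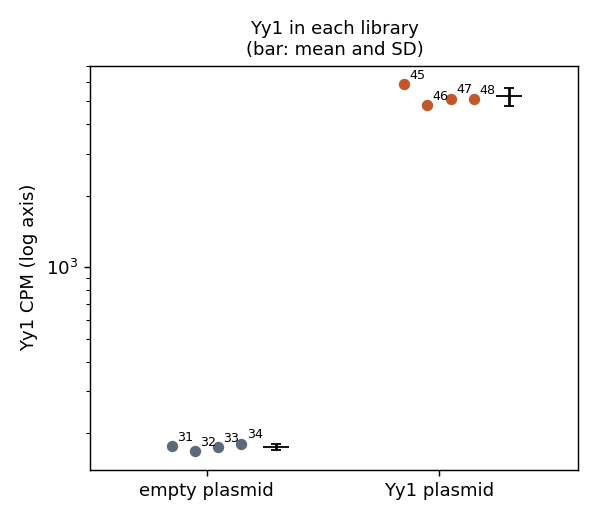
Yy1 level in each library, in CPM on a log axis. Points are libraries with their sample numbers, and the bar beside each group is its mean and SD (n = 4). The Yy1 libraries lie between 4814 and 5897 CPM and the empty plasmid libraries between 168 and 180.9 CPM.

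The main hormone gene of the alpha cell did not pass the test. Gcg, which encodes proglucagon, stood at 21230 ± 544 CPM with the empty plasmid and 21290 ± 371 CPM with the Yy1 plasmid (SD, n = 4), a log2 fold change of 0.0043 (SE 0.0448; edgeR adjusted p = 0.997). Among the 22 tested members of the alpha cell identity list, 0 were called by edgeR, and 2 had an unadjusted p under 0.05. St18, a zinc finger factor, had a log2 fold change of 0.11 (SE 0.0486). The log2 fold changes of the 22 members ran from -0.161 to 0.105.

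Apart from Yy1, few protein-coding genes were called. Of 15916 tested genes, edgeR called 82 at an adjusted p under 0.05, of which 79 were higher and 3 lower with the Yy1 plasmid. All 82 had libraries that did not overlap between the groups. This held for 628 of all tested genes, or 3.95%, where chance gives 2.86% for 4 against 4. An unadjusted p under 0.05 was found for 862 genes, 514 of them higher. Protein-coding genes made up 12466 of the tested genes and 12 of the called ones, and 90.9% of the tested protein-coding genes had an absolute log2 fold change under 0.2. Only Yy1 met the naming rule for genes with large changes, which needed an average log2 CPM of at least 2. Other called protein-coding genes named here were therefore chosen after their values were seen.

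The smallest p among them belonged to P2rx7, an ATP-gated cation channel, which rose from 0.670 ± 0.236 to 4.90 ± 0.190 CPM (SD, n = 4; log2 fold change 2.83, SE 0.187, edgeR adjusted p = 1.71e-09). Slfn5, a member of the interferon-inducible Schlafen family, rose from 0.903 ± 0.164 to 3.51 ± 0.522 CPM (SD, n = 4; log2 fold change 1.95, SE 0.190, edgeR adjusted p = 8.22e-07). Ren1, which encodes renin, had 4, 1, 1 and 2 counts with the empty plasmid and 51, 43, 56 and 69 with the Yy1 plasmid (log2 fold change 4.43, SE 0.371, edgeR adjusted p = 6.02e-08). A further 4 higher genes had group means of at most 1.02 CPM. They were Mybpc1, a sarcomere protein gene (log2 fold change 3.25, SE 0.479), Tmprss9, a membrane serine protease gene (3.11, SE 0.477), Apobr, a lipoprotein receptor gene (2.48, SE 0.408), and Ptcra, which encodes the pre-T cell receptor alpha chain (1.80, SE 0.343). The call of Ptcra was lost without empty plasmid 32 (edgeR adjusted p = 0.05) or Yy1 plasmid 47 (edgeR adjusted p = 0.0593).

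The 3 genes called lower were Hbb-bh1, Gm20605 and Gm45713. Hbb-bh1, an embryonic beta-like globin gene, had 11, 10, 9 and 13 counts with the empty plasmid and 0, 0, 2 and 2 with the Yy1 plasmid (log2 fold change -3.53, SE 0.642, edgeR adjusted p = 0.00457). Gm20605 had a log2 fold change of -0.48 (SE 0.0988; edgeR adjusted p = 0.0213) and Gm45713 of -1.24 (SE 0.270; edgeR adjusted p = 0.0307). Neither of these calls was stable when single libraries were left out. The call of Gm20605 was lost without empty plasmid 31, 32 or 34 or Yy1 plasmid 46, 47 or 48. That of Gm45713 was lost without empty plasmid 33 or Yy1 plasmid 45, 46 or 48.

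Gene models without a symbol in the reference annotation made up most of the genes called higher. They were 1561 of the tested genes and 58 of those called, and all 58 were higher with the Yy1 plasmid. Leaving Yy1 out, 3.72% of the tested models without a symbol were called higher, against 0.635% of annotated genes of other types and 0.0642% of protein-coding genes. Fisher's exact test, which counts genes that are not independent replicates, gave an odds ratio of 27.6 for models without a symbol (p = 3.46e-42). For annotated genes of types other than protein coding, of which 12 were called and all were higher, the odds ratio was 1.35 (Fisher's exact test, p = 0.377). Each class was set against all other tested genes, so here the reference held the 58 called models without a symbol. This ratio therefore does not compare the class with protein-coding genes alone, where the shares were 0.635% and 0.0642%. The median log2 fold change of the 58 was 1.502, with a range from 0.49 to 4.28. These transcripts were rare: over the 78 genes called higher besides Yy1, the median level was 0.659 CPM with the empty plasmid and 1.91 CPM with the Yy1 plasmid. Their levels summed to 102 and 276 CPM. The noncoding gene Gm10827, singled out here after its values were seen for its level, rose from 7.86 ± 1.37 to 21.7 ± 1.28 CPM (SD, n = 4; edgeR adjusted p = 1.04e-09). Among models without a symbol, ENSMUSG00000134131 rose from 2.61 ± 0.172 to 8.26 ± 0.82 CPM (SD, n = 4; edgeR adjusted p = 4.33e-09), and it too was chosen after its values were seen. The number called higher was 52 with a filter of 1 CPM in at least 4 libraries and 151 with no filter on low counts. It was 19 when only genes with a symbol were tested. The split of the same libraries by odd and even sample number gave 84 called genes, none of them among these 82, and with that split as a term in the model 80 genes were higher and 6 lower.

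**Figure D2:**
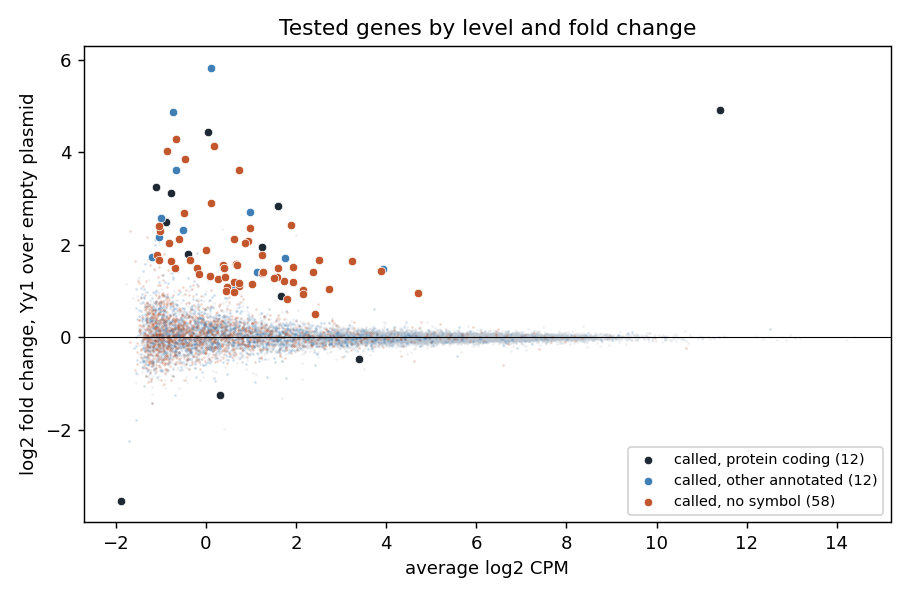
Log2 fold change, Yy1 over empty plasmid, against average log2 CPM for the 15916 tested genes. Large points are the 82 called genes by class: 12 protein coding (black), 12 of other annotated types (blue) and 58 without a symbol (orange). Small points are the remaining tested genes, and 12 of the called genes, Yy1 among them, have an average log2 CPM of 2 or more.

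Genes were also compared in lists fixed before the data were examined. Of 928 distinct tested members of the 31 lists that could be tested, edgeR called 0 over all genes. Adjusted over the list alone, 6 members passed, 5 in the hypoxia list and 1 in the list of the ATF4 stress response. Limma's camera with a preset correlation of 0.01 called 4 lists, 2 higher and 2 lower with the Yy1 plasmid. With an estimated correlation camera called 0 lists, and fry called 0 by direction.

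Genes induced by low oxygen formed the list with the smallest p. Of its 22 tested members, 21 had negative log2 fold changes and 9 of these had an unadjusted p under 0.05, while 0 passed over all genes. The members' mean log2 CPM was 6.42 with the empty plasmid and 6.29 with the Yy1 plasmid, a difference of -0.133 (SE 0.0624, n = 4 per group; camera adjusted p = 8.27e-08). With an estimated correlation the list was not called (adjusted p = 0.458), and the exact permutation test of the list's mean gave a two-sided p of 0.0571. The 5 members that passed adjusted over the list alone were Pdk1, Kdm3a, Adm, Hk2 and Vegfa, each with an adjusted p of 0.0462 on that scale. Vegfa lies outside the naming rule and was chosen after its values were seen. Their log2 fold changes were -0.16 for Pdk1, a kinase that restrains pyruvate oxidation, -0.12 for Kdm3a, a histone demethylase, and -0.38 for Adm, which encodes adrenomedullin. Hk2, a hexokinase, had -0.19 and Vegfa, an angiogenic growth factor, had -0.13. Empty plasmid 32 had the highest mean, 6.60, and without it the mean fitted log2 fold change of the list went from -0.139 to -0.077 (camera adjusted p = 0.00118).

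**Figure D3:**
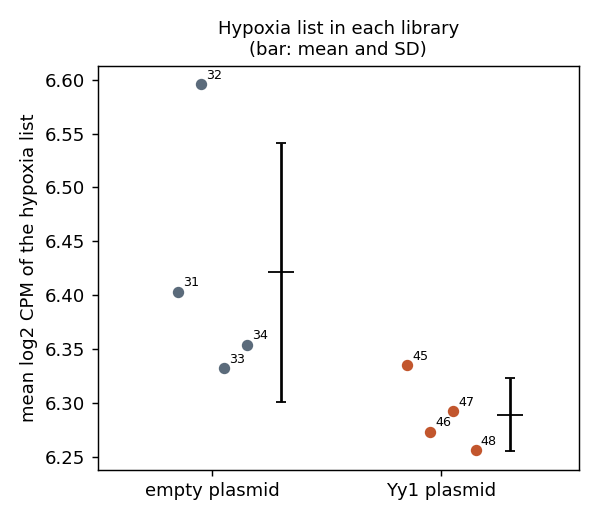
Mean log2 CPM of the 22 tested members of the hypoxia list in each library. Points are libraries with their sample numbers, and bars are group means and SD (n = 4). Values run from 6.332 to 6.596 with the empty plasmid and from 6.256 to 6.335 with the Yy1 plasmid, and the axis does not start at 0.

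Metabolic lists moved little. Nuclear OXPHOS subunits, which build the respiratory chain, were called higher by camera with a mean difference of 0.03 (SE 0.0342; 78 members; camera adjusted p = 0.0174), with an adjusted p of 0.744 with an estimated correlation. The exact permutation test of its mean gave a two-sided p of 0.371. The call was also lost with DESeq2 (camera adjusted p = 0.191), with no filter (0.437) and without empty plasmid 32 or 34 or Yy1 plasmid 45 or 47 (camera adjusted p from 0.129 to 0.392), and the list was lower in even than in odd sample numbers (mean log2 fold change -0.083; camera adjusted p = 1.18e-11, or 0.193 with an estimated correlation). With odd or even number as a term the call between the plasmids was kept (camera adjusted p = 0.00279). Members with the smallest p were Uqcr11 (log2 fold change 0.14, SE 0.0494), Ndufa11 (0.14, SE 0.0564), Ndufb4 (0.19, SE 0.0882) and Cox6c (0.09, SE 0.0461). The 13 genes of mitochondrial DNA were not called (camera adjusted p = 0.486), and the largest difference among the named ones was in mt-Nd6, with a log2 fold change of -0.32 (SE 0.129). The list of glycolysis and the TCA cycle had a mean difference of -0.0428 (camera adjusted p = 0.0806). It was called lower with limma-voom (0.0219) and without empty plasmid 31 (0.0386) or 34 (0.00944), all with the preset correlation, and had an adjusted p of 0.744 with an estimated one. It shares Pdk1, Hk2 and Ldha with the hypoxia list, and Ldha, which encodes lactate dehydrogenase A, had a log2 fold change of -0.15 (SE 0.0597). Cholesterol synthesis (camera adjusted p = 0.414), amino acid metabolism (0.641), mitochondrial biogenesis (0.532), and the mitochondrial (0.973) and cytosolic (0.641) ribosomes were not called, although the last was called higher without empty plasmid 33 (camera adjusted p = 0.0139 with the preset correlation). With an estimated correlation, which was 0.504 for that list, its adjusted p over all libraries was 0.931. Rps12, a protein of the small ribosomal subunit, had a log2 fold change of 0.32 (SE 0.0848; edgeR adjusted p = 0.241). For the mitochondrial ribosome the mean difference was -5e-04, while the median was 0.003 and camera's direction was higher.

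Of the proliferation lists, only that of S phase was called. The list, which holds replication factors, was called lower by camera with a mean difference of -0.0325 (SE 0.0276; 40 members; camera adjusted p = 0.0199), with an adjusted p of 0.744 with an estimated correlation. The exact permutation test of its mean gave a two-sided p of 0.371. The call was also lost with no filter (camera adjusted p = 0.0779) and without empty plasmid 31 or 33 or Yy1 plasmid 45 or 46 (camera adjusted p from 0.0753 to 0.299), and the list was lower in even than in odd sample numbers (mean log2 fold change -0.055; camera adjusted p = 2.99e-05, or 0.583 with an estimated correlation). The S phase call was kept with odd or even number as a term (camera adjusted p = 0.0086). Of its members, 33 had negative log2 fold changes and 0 had an unadjusted p under 0.05. Mcm4 and Mcm6, subunits of the replicative helicase, both had a log2 fold change of -0.07 (SE 0.0387 and 0.0419). The list of G2 and M phase was not called (camera adjusted p = 0.418), nor were replication-dependent histones (0.552) or p53 targets (0.831).

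Markers of other cell types gave 1 further call. The list of acinar and ductal cells had 7 tested members of 22, all with positive log2 fold changes and with a mean difference of 0.18 (SE 0.0501; camera adjusted p = 0.0174), with an adjusted p of 0.415 with an estimated correlation. The exact permutation test of its mean gave a two-sided p of 0.0286. The call was also lost without empty plasmid 31 (camera adjusted p = 0.0704) or 34 (0.132), when thinned to the smallest depth (0.0587), with DESeq2 (0.071) and with no filter (0.152). Sox9, a progenitor and duct factor, stood at 3.95 ± 0.402 and 4.76 ± 0.462 CPM (SD, n = 4; log2 fold change 0.27, SE 0.125). Spp1, which encodes osteopontin, had a log2 fold change of 0.23 (SE 0.114). None of the 7 passed adjusted over the list alone. Other islet endocrine genes were not called (camera adjusted p = 0.24), with a mean difference of 0.138 (SE 0.0593; two-sided exact permutation p = 0.0286). Mafa, a beta cell factor, had a log2 fold change of 0.98 (SE 0.430) at an average log2 CPM of -1.06. Of 22 stromal, endothelial and immune markers only 4 were tested, so this list had no camera test. Their summed level was 7.74 ± 1.6 CPM with the empty plasmid and 7.34 ± 1.05 CPM with the Yy1 plasmid (SD, n = 4; two-sided exact permutation p = 0.686).

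Stress and signalling lists were not called by camera. In the ATF4 list (camera adjusted p = 0.218), Nupr1, a stress-induced chromatin protein, had a log2 fold change of -0.28 (SE 0.0777) and passed adjusted over the list alone (adjusted p = 0.0333), and Atf4 itself had -0.08 (SE 0.0364). Fry's mixed test, which asks whether members change in either direction, called the ATF4 list (adjusted p = 0.00123) and the interferon list (adjusted p = 0.00149; camera adjusted p = 0.414). The mixed test was run only with the main settings and all libraries. Its calls were thus not checked under the alternatives, without single libraries or in other splits. In the interferon list Stat2 had a log2 fold change of -0.13 (SE 0.0536) and Irf1 of -0.11 (SE 0.0548). Of its 22 tested members 13 had negative and 9 had positive log2 fold changes, from -0.6 to 0.761. Among immediate early genes (camera adjusted p = 0.614), Jun had a log2 fold change of -0.20 (SE 0.0595) and Junb of -0.18 (SE 0.0724). Egr3 had 0.85 (SE 0.406), and the list's median of -0.003 and mean of 0.06 differ in sign. The other camera adjusted p values were 0.643 for chaperones of the endoplasmic reticulum, 0.735 for NF-kB and inflammation, 0.567 for antigen presentation, 0.0696 for NRF2 targets and 0.218 for lysosome and autophagy. The NRF2 list was called higher by camera in 8 alternatives, with adjusted p of 0.0402 with upper-quartile scaling, 0.0138 with the 1 CPM filter and 0.0254 with limma-voom. The others were 0.0248 with 1 surrogate variable, 0.0196 when thinned, 0.0235 with symbols only, 0.0135 with coding genes only and 0.028 without empty plasmid 33. All 8 used the preset correlation. Over all libraries the list had an adjusted p of 0.415 with an estimated correlation, which was 0.002, and of 0.117 with fry. Its mean difference was 0.0309 (SE 0.0204; two-sided exact permutation p = 0.286). In antigen presentation, B2m, the light chain of class I molecules, had a log2 fold change of 0.17 (SE 0.0544; edgeR adjusted p = 0.375).

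Partners and functions tied to Yy1 were covered by lists of the YY1 family with INO80 and Polycomb complexes (camera adjusted p = 0.364) and of chromatin looping with Mediator (0.256), neither of which was called. Ldb1, an adaptor of enhancer loops, had a log2 fold change of -0.10 (SE 0.0394) and Med17, a Mediator subunit, had -0.13 (SE 0.0586). Lists of hormone granules and exocytosis (camera adjusted p = 0.326) and of excitability and nutrient sensing (0.521) were not called either. In the former, 20 of the 32 tested members had positive log2 fold changes and 12 had negative ones. The member with its smallest p, Unc13a, which primes secretory vesicles, had a log2 fold change of -0.14 (SE 0.0510; edgeR adjusted p = 0.572). In the list of excitability, Abcc8 and Kcnj11, the subunits of the ATP-sensitive potassium channel, had -0.06 (SE 0.0383) and -0.06 (SE 0.0380). Cilium and Hedgehog signalling (0.28), extracellular matrix and adhesion (0.0806), and TGF-beta and Wnt targets (0.851) completed the lists. That of extracellular matrix was called higher when only genes with a symbol (camera adjusted p = 0.0451) or only coding genes (0.029) were tested, both with the preset correlation. Over all genes it had an adjusted p of 0.415 with an estimated correlation, which was -0.018.

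**Figure D4:**
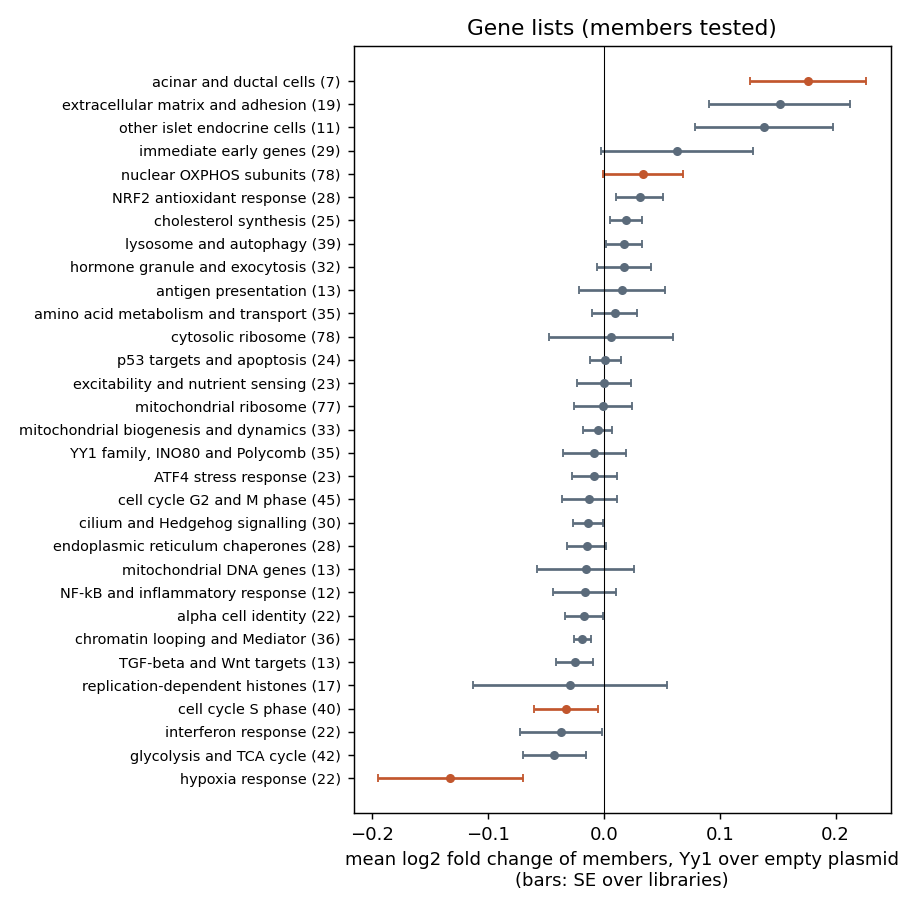
Mean log2 fold change, Yy1 over empty plasmid, of the tested members of each of the 31 tested lists, with the number of members in parentheses. Bars are SE over libraries (n = 4 per group). Orange marks the 4 lists called by camera with the preset correlation, from -0.1325 for hypoxia to 0.1762 for acinar and ductal cells.

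More genes were detected with the Yy1 plasmid. With all libraries thinned to the smallest total, 26183 ± 220 genes had a count above 0 with the empty plasmid and 27149 ± 251 with the Yy1 plasmid (SD, n = 4), a difference of 966.2 genes (two-sided exact permutation p = 0.0286, the smallest possible). The same difference was 276 for protein-coding genes, 240.8 for other annotated types and 449.5 for models without a symbol, each with an exact permutation p of 0.0286. The share of counts in models without a symbol was 1.22 ± 0.0932% with the empty plasmid and 1.21 ± 0.0355% with the Yy1 plasmid (SD, n = 4; two-sided exact permutation p = 0.914). Genes of mitochondrial DNA took 7.88 ± 0.484% and 7.74 ± 0.193% of counts (SD, n = 4; two-sided exact permutation p = 0.657).

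**Figure D5:**
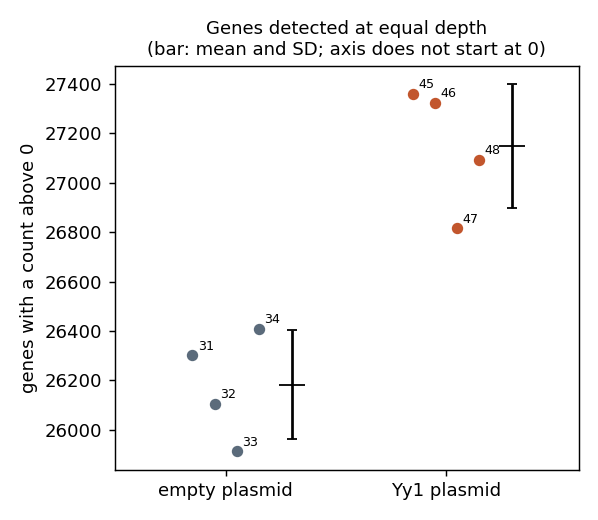
Genes with a count above 0 in each library after thinning to the smallest total. Points are libraries with their sample numbers, and bars are group means and SD (n = 4). The Yy1 libraries lie between 26817 and 27361 and the empty plasmid libraries between 25913 and 26410, and the axis does not start at 0.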

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

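Tests of shared sequence, depth, an even rise and repeats, and that of the called genes as the source of more detected genes, were chosen only after the results were seen. Of 24 groups of 4 libraries checked for a value far from the others, 1 stood out, and chance gives about 1 in 20. In the list of acinar and ductal cells, Yy1 plasmid 48 had a mean log2 CPM of 1.851, below the nearest Yy1 library at 1.949.

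Models without a symbol dominated the genes called higher with the Yy1 plasmid. Greater depth of the Yy1 libraries is argued against, since 68 of the 79 genes called higher remained so after thinning. An even rise of such models by about as much as the called ones is argued against as well. The called ones had a median log2 fold change of 1.502 and a lowest of 0.492, values raised by their choice for a small p. All 1561 tested ones, called ones included, had a median of 0.042 (95% bootstrap limits 0.028 and 0.054), with quartiles of -0.125 and 0.275. A small rise of them all, of about that median, is left open by the test. This test replaced a first form on the models that were not called, which could decide nothing because it left out the called ones. Reads shared with the Yy1 transcript are argued against for annotated genes, of which 0 of 20 share a 31-mer with Yy1 (upper 95% exact limit 16.8%), and stay open for the 58 models without a symbol, for which sequence at hand covered 0. B1 or B2 repeats occurred in 9 of the 20 annotated genes against a median of 4 in 10000 matched draws. The one-sided p of these permutation draws was 0.0061. The 58 models without a symbol could not be searched for repeats, for want of sequence. Among uncalled annotated genes of types other than protein coding, the median log2 fold change was 0.04 for 374 with a repeat. It was 0.017 for 1503 without one. Repeats in the annotated genes, regulation by Yy1 itself or a difference in handling between the groups may each account for some of the rise. None was separated from the others here.

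More genes were detected at equal depth with the Yy1 plasmid. The called genes alone are argued against by their number, since 82 genes cannot make up a difference of 966.2 genes. Carry-over of DNA that reaches silent genes stays open: summed levels of 1665 olfactory and vomeronasal receptor genes were 1.13 times as high with the Yy1 plasmid (95% counting interval 1.08 to 1.17), against 1.16 for untested models without a symbol. Between libraries the receptor levels overlapped, with 45.6 ± 4.72 CPM against 51.6 ± 3.2 CPM (SD, n = 4; two-sided exact permutation p = 0.0571). They did not overlap for the untested models without a symbol, with 523 ± 19.7 against 609 ± 23.8 CPM, or for 9246 untested protein-coding genes, with 390 ± 26.7 against 446 ± 13.3 CPM (SD, n = 4; two-sided exact permutation p = 0.0286 for each). The coding genes had a ratio of 1.13 (95% counting interval 1.12 to 1.15), which lies below 1.16. Such carry-over, or an effect of Yy1 on silent genes, could each give this, and the 2 cannot be told apart because the interval of the receptors, which covers counting error only, holds 1.16. The lower ratio of coding genes does not settle it, since their own transcription was not measured apart from DNA.

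The hypoxia list was lower with the Yy1 plasmid under the preset correlation. The list stayed called and lower in all 8 fits that leave 1 library out, with a highest camera adjusted p of 0.00118. These fits used the preset correlation of 0.01, while the estimated one was 0.534 for this list. They therefore cannot decide whether a single library is the cause, and the size of the difference dropped most without empty plasmid 32. A difference in culture between the sets of wells, such as cell density, cannot be told apart from an effect of the plasmid, since the labels give no handling of the wells, and with an estimated correlation the adjusted p was 0.458. Across 24 alternatives the adjusted p ran from 1.94e-12 to 0.458.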

How the results depend on the processing

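Settings added after seeing the data were thinning, genes with a symbol only, protein-coding genes only, and odd or even number as a term. The Yy1 call kept its direction and its side of the threshold in each alternative run, with log2 fold changes from 4.838 without Yy1 plasmid 45 to 4.938 without Yy1 plasmid 46. Genes higher numbered 79, and became 151 with no filter, 52 with the 1 CPM filter, 19 with symbols only and 9 with coding genes only, where fewer or more genes were tested. With 1 library left out they ran from 60 to 83. Genes lower numbered 3, and became 23 with no filter, 6 with DESeq2, 8 with 1 surrogate variable, 1 with glmTreat, 1 with symbols only, 1 with coding genes only and 6 with odd or even number as a term. With 1 library left out they ran from 2 to 7 (7 without Yy1 plasmid 45, 5 without 47, 6 without empty plasmid 33). Lists called numbered 4, and became 1 with no filter, 2 with DESeq2, 0 with an estimated correlation and 0 with fry. They rose to 5 with upper-quartile scaling, the 1 CPM filter or 1 surrogate variable, and to 6 with limma-voom, symbols only or coding genes only. With 1 library left out they ran from 2 (without Yy1 plasmid 45) to 5 (without empty plasmid 33). For the remaining changes the cause was not tested. Other scalings moved the median of all genes by under 0.01.

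The rest concerns means of fitted log2 fold changes of lists that were not called, and 0 of the 72 changed signs came with a call. Signs changed in 16 lists and in Gcg. With no filter, where rare members enter, the means were 0.179 for alpha cell identity, -0.085 for other islet endocrine cells, 0.047 for ATF4, 0.413 for NF-kB, -0.02 for antigen presentation, -0.092 for p53, 0.035 for the YY1 family, 0.104 for cilium, -0.028 for extracellular matrix and 0.102 for TGF-beta and Wnt. With DESeq2, tested without that filter, they were 0.142 for alpha cell identity, -0.0027 for mitochondrial ribosome, -0.00069 for cytosolic ribosome, 0.045 for ATF4, 0.0077 for interferon, 0.342 for NF-kB, -0.028 for antigen presentation, -0.105 for p53, 0.072 for cilium, -0.036 for extracellular matrix and 0.089 for TGF-beta and Wnt. With the 1 CPM filter they were -0.007 for excitability, 0.0014 for interferon, 0.0094 for NF-kB and -0.0027 for p53. Mitochondrial ribosome had -0.0021 with library size alone, -0.0016 with a mean count of 10, -0.0013 with Yy1 left out and -0.0022 thinned. In the first 3 of these p53 had -0.00097, -0.00017 and -2e-05, and thinned NF-kB had 0.036. Fits with 1 library left out tested from 16211 to 16363 genes, against 15916 with all libraries. The tested members of a list can thus differ there, as well as the libraries. With 1 library left out, means ran from -0.019 to 0.013 for ATF4, -0.042 to 0.031 for NF-kB, -0.04 to 0.02 for TGF-beta and Wnt, -0.025 to 0.01 for the YY1 family, -0.0046 to 0.022 for amino acid metabolism, -0.018 to 0.032 for antigen presentation, -0.028 to 0.0086 for G2 and M phase, -0.027 to 0.038 for cytosolic ribosome, -0.028 to 0.02 for excitability, -0.015 to 0.015 for mitochondrial ribosome and -0.055 to -0.037 for p53, and Gcg from -0.0076 to 0.015. Over all alternatives 20 calls of named genes were lost and 5 gained, and 24 calls of lists were lost and 14 gained, with no change of sign among these. The groups share no sample numbers, and no paired analysis was possible because the groups compared share fewer than 2 numbers. The promoter motif test was not run, nor were its alternatives.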

Other observations

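The length test of odd and even sample numbers was chosen only after the split was seen. The 8 libraries can be split into 4 and 4 in 35 ways, and 2 of these gave at least the 82 genes called between the plasmids. Chance is therefore not excluded by this count, with 84 genes in the highest other split. That split parts odd from even sample numbers and so holds both plasmids on each side. It points to a structure of the samples: of its 84 genes, 27 were higher and 57 lower in even numbers, and 0 were among those called between the plasmids. With odd or even number as a term, 86 genes were called between the plasmids, while the other splits with 2 odd and 2 even numbers on each side, 18 in all with the real one, gave at most 6. For lists, 19 of the 35 splits gave at least the 4 called ones, and the highest other split gave 8, so chance is not excluded as the source of the number of camera calls. With odd or even number as a term, 3 of the 18 splits, the real one included, gave at least 4 lists and the highest other gave 4. With only 18 splits, the real one among them, a share under 0.05 cannot be reached, so this count could not have excluded chance.

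Genes called lower in even sample numbers included 13 of the cytosolic ribosome list and 5 of the nuclear OXPHOS list. Camera with the preset correlation called 5 lists, with cytosolic ribosome (mean log2 fold change, even over odd, -0.129; adjusted p = 6.48e-26), nuclear OXPHOS subunits (-0.083; adjusted p = 1.18e-11), mitochondrial ribosome (-0.058; adjusted p = 4.45e-06) and S phase (-0.055; adjusted p = 2.99e-05) lower and mitochondrial DNA genes higher (0.078; adjusted p = 0.000135) in even numbers. With an estimated correlation camera called 0 of them, with adjusted p of 0.0621, 0.193, 0.0715, 0.583 and 0.205 in the same order. The nuclear OXPHOS and S phase lists are thus also among those called between the plasmids. The median transcript length was 1276 bases for coding genes called lower in even numbers and 10832 for those called higher. A bias by transcript length that alternates with the sample number, as in library preparation, is a candidate explanation: across 12466 protein-coding genes, which are not independent replicates, the difference followed length with a Spearman rho of 0.234 within the empty plasmid and 0.251 within the Yy1 plasmid. GC content gave 0.029 and -0.228, which leaves a GC bias open for the Yy1 libraries alone. Between the plasmids, the even over odd differences of these genes had a Spearman rho of 0.154, so gene by gene they were shared only weakly. No other split within a plasmid was compared for length. No biological explanation was tested, since the labels give none for the numbers.

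A hypothesis was that genes carrying a YY1 motif near the transcript start shift with the Yy1 plasmid. The motif ANATGGCGG lay in the first 200 bases of the longest transcript of 551 tested genes, and a scrambled motif, ANGTGGCAG, in that of 166. The motif genes had a median log2 fold change of -0.0069 against -0.0039 for other genes. Limma's camera with the preset correlation gave a p of 0.38 for them and of 0.387 for the scrambled set. With an estimated correlation camera gave 0.0995 and 0.211. Of the motif genes 0 were called higher and 0 lower by edgeR. Among all 14354 tested annotated genes besides Yy1, only 20 were called higher and 3 lower, so these counts cannot decide. Sequence upstream of the start was not searched.

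Yy1 plasmid 47 alone held more than 3 counts of 5 myeloid genes, chosen after their values were seen. It had 34 counts of S100a8, 54 of S100a9, 20 of Ngp, 23 of Chil3 and 15 of Ccl6, while no other library had more than 3 of any of them. Empty plasmid 33 lay apart from the other empty plasmid libraries on the second principal component of log2 CPM (18.3% of the variance), at 26.3 against -8.61, -20.7 and -17.5. On the first component (23.2%) it was also outermost, at -29.6 against -8.46, -12.4 and -9.11. That component parted the plasmids, with the Yy1 libraries from 13.4 to 16.6.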
